A study of Mus musculus with 4 samples.

How the data were processed

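Polyadenylated RNA from mouse macrophages grown from C57BL/6J bone marrow was sequenced in 4 libraries, all of 1 group: cells given a stimulus at 100 ng/mL for 60 minutes. The labels number them as biological replicates 1 to 4, with 1 technical replicate each. The labels do not name the stimulus the same way throughout: one field names lipid A, the part of bacterial lipopolysaccharide that Toll-like receptor 4 recognises, and other fields name lipoprotein A, so the stimulus is called the stimulus here. All 4 libraries carry the same donor label and nothing says that they came from separate animals or cultures, so p-values of the contrast between libraries measure only the spread between these samples, which may be technical. P-values of the tests over genes, transcripts or random lists and of the test against counting noise do not measure that spread. No unstimulated cells were analysed here, so every comparison is between genes, between gene lists or between libraries, and none of them measures a response to the stimulus.

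Each library had 3 deposited tables, 1 for genes and 2 for transcripts, all on the mouse genome build mm10 with the GENCODE M21 annotation, per the deposited text lists of files. The gene table and the first transcript table were made from a transcriptome alignment and have the column names that RSEM writes, and the second transcript table was made straight from the reads and has the column names that kallisto writes. The tools, their versions and the strand setting are not given in the sources used here. The deposited gene and transcript tables hold expected counts per the file headers, which are estimates and need not be whole where genes share reads. They also hold TPM values, transcript abundances on a relative scale, as a maximum likelihood estimate and as a posterior mean, which the authors scaled over all rows of a table. The deposited gene table further holds the lower and upper bounds of a credibility interval for the TPM, a non-negative signal whose level is not stated. The second transcript table holds deposited estimated counts and TPM, which were summed to genes and are called the second quantification; 86 genes of the gene table have no transcript in it. Of the 81881 rows of a gene table, 55536 were genes, and all 55536 identifiers matched GENCODE M21. The other rows were 96 ERCC spike-in rows and 26248 number-only rows, all at 0, and 1 phiX row, and they were left out of library sizes and tests. The phiX row held 0.113% ± 0.00679 (SD, n = 4) of all counts.

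The text lists name 6 read files for each of replicates 1 and 2 and 4 read files for each of replicates 3 and 4. This recorded difference was used as a technical contrast, although no source calls it a batch.

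Expected counts were rounded to whole numbers for count tests. Effective library sizes came from edgeR 4.0.16 (TMM) in R 4.3.3, with limma 3.58.1 loaded beside it, and DESeq2 1.42.0 gave alternative size factors and an alternative test. The rest was computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The common biological coefficient of variation came from edgeR with an intercept-only model on genes kept by its own expression filter, with a jackknife standard error over the 4 libraries. Variation beyond counting noise was tested per gene by a chi-square test with 3 degrees of freedom on genes with a mean count of at least 10, with Benjamini-Hochberg adjustment at 0.05. A gene was called variable when it passed and its highest and lowest scaled counts also differed at least 2-fold. Counts of sequenced fragments are not independent molecules, so this test covers counting error only.

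Before the data were examined, 28 gene lists, 16 comparisons between lists and the rules for naming genes were fixed. For each comparison, genes in both lists were dropped, and the difference of medians of log2(mean TPM + 0.1) was tested with a 2-sided permutation test over genes with 100000 resamples, adjusted over the 16 comparisons; genes are not independent replicates, so the range of the difference in single libraries is also given. The median gene of a mean can differ from that of a single library, so the difference can lie outside this range. List differences are on the log2(TPM + 0.1) scale, which understates differences for genes near 0. The spread of a list between libraries was the median over its genes of the SD over 4 libraries of log2(CPM + 1). It was set against 10000 random lists of the same size matched on mean level in bins of 50 genes. Lists with at least 5 tested genes entered, which were 23. A second statistic on the same random lists, the SD over libraries of the median, over members, of each gene's deviation from its own mean, was added after the data were seen; it measures whether the members moved in the same direction. Permutation p-values cannot go below 1e-05. P-values from random lists, called random-list p, cannot go below 0.0001 (0.0002 when 2-sided).

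The genes named were, for each list, the 2 with the highest mean TPM and the 1 with the highest ratio of the highest to the lowest library. To these were added a fixed set of inflammatory, interferon, macrophage and sex-linked genes, the 15 nuclear genes with the highest mean TPM, the 15 protein-coding genes with the highest ratio among variable genes with a mean count of at least 100, and a fixed set for isoforms. Other list members named as examples were chosen after their values were seen, and some items that meet these rules are not reported here. A symbol carried by more than 1 identifier was given to the one with the highest mean TPM.

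The tests named next were tested on simulated data; the DESeq2 contrast, Fisher's tests and Dixon's ratio were not. The chi-square test, run on 12621 genes with Poisson counts at the real means, recovered 100.0% of 100 genes changed 3-fold in 1 library and 100.0% of 100 genes changed 6-fold, and called 2 unchanged genes. The edgeR contrast of 2 with 2 libraries, run on 12701 genes, recovered 4.0% of 100 genes changed 2-fold and 67.0% of 100 genes changed 4-fold, and called 5 unchanged genes. The list permutation test passed 0.05 in 1 of 60 draws without a difference and in 95.0% of 20 draws with an 8-fold difference. The test of a list's shift passed in 1 of 20 random lists and in 100.0% of 20 lists given a shared shift. The test of a list's spread passed in 1 of 20 random lists and in 100.0% of 20 lists given added spread. Only a single size of shift and of spread was added, so recovery of smaller ones is not known.

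Gene counts totalled 26917324, 30042947, 35277710 and 39438414 in replicates 1 to 4. A gene with a count of 0 can lie at up to 0.111 CPM in the shallowest library and 0.0761 CPM in the deepest, which is the level of 3 counts. Alternatives covered TPM minimums, pseudocounts, filters, posterior mean TPM, the second quantification, DESeq2 size factors and each library left out in turn. Added after the data were seen were the libraries with the same number of read files taken alone, TPM rescaled without ribosomal and mitochondrial genes, and a removal of the trend on GC content and transcript length. In the read file contrast, the second quantification and other pairings of the libraries were also added then.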

Results

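The data describe the transcriptome of mouse bone marrow-derived macrophages, primary phagocytes grown from marrow precursors, 60 minutes after a stimulus of 100 ng/mL. The labels name the stimulus both as lipid A, a Toll-like receptor 4 ligand, and as lipoprotein A. All 4 libraries belonged to this 1 group, so the questions the data can answer are which genes stood at which level in these cells and how far the 4 libraries differed. Total gene counts ranged from 26917324 in replicate 1 to 39438414 in replicate 4. In every library 10250 genes reached 1 TPM, of which 9641 were protein-coding. Values are TPM as mean ± SD over 4 libraries unless stated, and coordinates are on mm10 with GENCODE M21.

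Cytokine and chemokine transcripts of the primary inflammatory list were among the most abundant messages of these cells. Tnf, which encodes the cytokine TNF, stood at 5552 ± 1022 TPM (SD, n = 4) and ranked 15 among protein-coding genes. Next in level within the list were the chemokine gene Cxcl2 at 3394 ± 347 TPM, the interleukin-1β gene Il1b at 2923 ± 697 TPM, Ccl4 at 2906 ± 1243 TPM and Ccl3 at 2707 ± 650 TPM. All 24 members of the list reached 1 TPM in every library and 22 had a mean of at least 100 TPM. The median member stood at 1202 TPM. Tnf (ENSMUSG00000024401.14) lies on chromosome 17 from 35199381 to 35202007, Il1b (ENSMUSG00000027398.13) on chromosome 2 from 129364570 to 129371139, and Cxcl2 (ENSMUSG00000058427.10) on chromosome 5 from 90903871 to 90905938.

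Genes that are known to follow later in inflammatory activation stood far lower. In the late inflammatory list 12 of 16 members reached 1 TPM in every library, and 1 member, the chemokine gene Ccl5 at 442.2 ± 162 TPM, had a mean of at least 100 TPM. Il6 stood at 22.5 ± 19.5 TPM, Il12b, which encodes the p40 subunit of interleukin-12, at 65.49 ± 44.3 TPM, and Nos2, the inducible nitric oxide synthase gene, at 0.38, 0.5, 1.49 and 2.51 TPM in replicates 1 to 4. On the log2(TPM + 0.1) scale used for comparisons, where the medians correspond to 1197 and 15.9 TPM, the primary list exceeded the late list by 6.23 log2 units or 74.8-fold (5.68 to 6.67 log2 units in single libraries), with a permutation p of 1e-05, the smallest the test can give, and 2.29e-05 after adjustment.

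The remaining response lists lay between these. Members of the immediate-early list, mostly transcription factor genes of a kind known to be induced without new protein synthesis, had a median of 143.0 TPM. Junb stood at 1000.0 ± 313 TPM, Atf3 at 708.2 ± 206 TPM, Egr1 at 228.2 ± 28.9 TPM and Fos at 210.4 ± 46.5 TPM. Among negative feedback genes, which restrain NF-κB, kinases or cytokine messages, the median was 142.0 TPM, with the IκBα gene Nfkbia at 1937 ± 315 TPM, the mRNA-destabilising factor gene Zfp36 at 1454 ± 472 TPM, the A20 gene Tnfaip3 at 958.3 ± 152 TPM and the phosphatase gene Dusp1 at 939.4 ± 154 TPM. All 24 negative feedback genes reached 1 TPM in every library. Interferon-stimulated genes had a median of 86.0 TPM, and all 25 reached 1 TPM in every library. Primary inflammatory genes exceeded negative feedback genes by 3.18 log2 units (2.74 to 3.52 in single libraries, adjusted permutation p = 9.33e-05) and interferon-stimulated genes by 3.8 (3.47 to 4.52, adjusted permutation p = 2.29e-05). Immediate-early genes exceeded late inflammatory genes by 3.16 log2 units (2.7 to 3.54, adjusted permutation p = 0.00441), and interferon-stimulated genes exceeded them by 2.43, with a lower difference of 2.16 to 2.4 in single libraries (adjusted permutation p = 0.000431). Each of these 4 differences had the same sign in 4 of 4 libraries. Without unstimulated cells, these levels do not separate induced from standing transcripts.

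**Figure D1:**
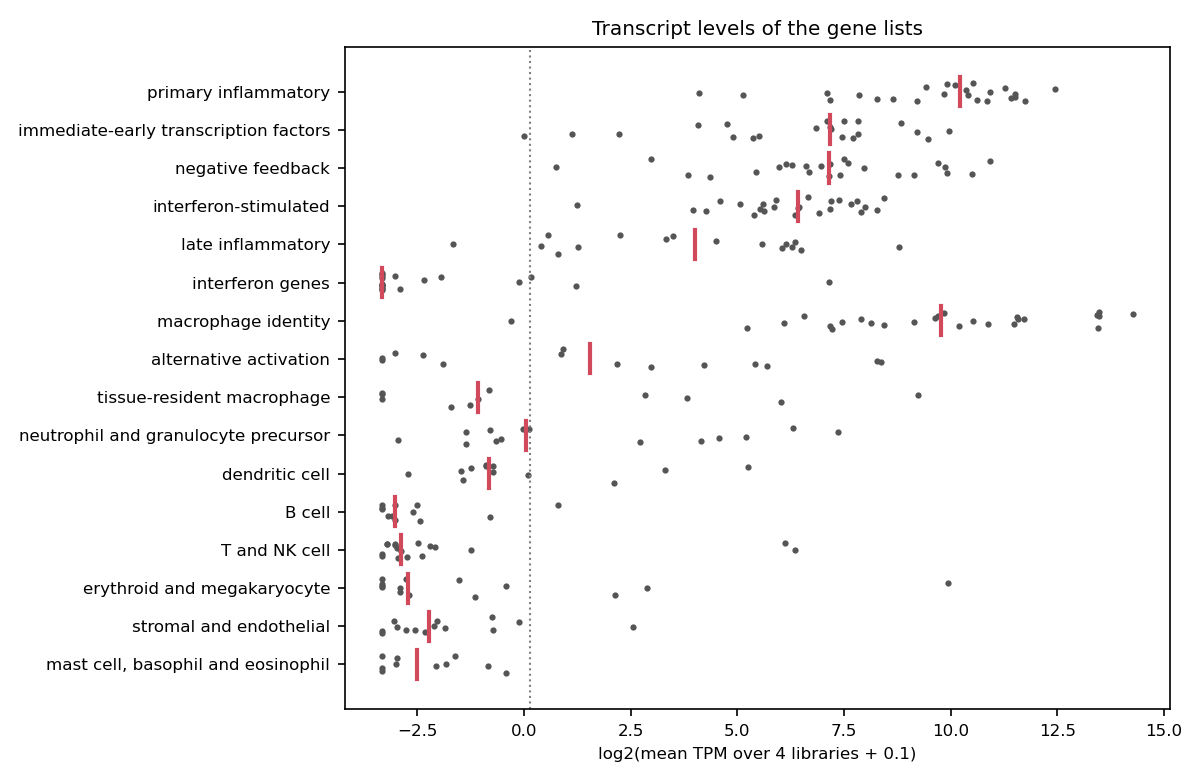
Each point is 1 gene, placed by log2(mean TPM over 4 libraries + 0.1) on the horizontal axis and by gene list on the vertical axis, and red bars are list medians; the dotted line marks 1 TPM. The median of the primary inflammatory list lies at 1202 TPM, above that of the late inflammatory list at 16.9 TPM, and the lists of other cell types lie below 1 TPM at their medians.

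Among interferon genes themselves, Ifnb1 was the single abundant one. It stood at 49.87, 179.7, 74.57 and 262.7 TPM in replicates 1 to 4, and Ifnb1 (ENSMUSG00000048806.4) lies on chromosome 4 from 88522025 to 88522774. Of the 19 interferon genes in the list, 15 were below 1 TPM in every library and 11 had a count of 0 in every library, which allows up to 0.111 CPM in the shallowest. Ifna2 reached 6.66 TPM in replicate 4 and 0.07 TPM in replicate 1, values that are uncertain because the interferon alpha genes are near-identical and share reads.

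Receptors for bacterial ligands were present. Cd14, the co-receptor that passes lipopolysaccharide to Toll-like receptor 4, stood at 1461 ± 397 TPM, Tlr4 at 38.38 ± 2.2 TPM and Tlr2, a receptor for bacterial lipoproteins, at 397.5 ± 179 TPM. Of 28 genes of the Toll-like receptor 4 pathway, 27 reached 1 TPM in every library, with a median of 39.7 TPM. The other Toll-like receptor genes had a median of 34.5 TPM, and the difference of 0.2 log2 units (-0.18 to 0.73 in single libraries) did not pass the test (permutation p = 0.742 before and after adjustment, higher in 2 of 4 libraries). This difference had the opposite sign, -0.27 log2 units, when genes below 0.1 TPM were left out.

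The cells carried the transcripts of macrophages, and lists of genes of other marrow or tissue cells stood low at their medians. The lysozyme gene Lyz2 stood at 19685 ± 6749 TPM, the cathepsin gene Ctsd at 11346 ± 1093 TPM, Csf1r, the receptor of the growth factor that maintains macrophages, at 789.5 ± 279 TPM, and Adgre1, which encodes F4/80, at 563.8 ± 61.1 TPM. Of 26 macrophage identity genes, 25 reached 1 TPM in every library; the exception was Cx3cr1 at 0.705 ± 0.772 TPM. Their median was 875.0 TPM. The median was 0.0225 TPM for B cell genes, 0.035 TPM for T and NK cell genes, 0.0513 TPM for erythroid and megakaryocyte genes, 0.0838 TPM for mast cell, basophil and eosinophil genes, 0.115 TPM for stromal and endothelial genes, 0.471 TPM for dendritic cell genes and 0.935 TPM for neutrophil and granulocyte precursor genes. Differences of macrophage identity genes from these 7 lists ran from 9.72 log2 units for the neutrophil list (9.09 to 11.36 in single libraries) to 12.8 for the B cell list (12.75 to 13.29), with adjusted permutation p-values from 2.29e-05 to 5.82e-05 and the same sign in 4 of 4 libraries for each.

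Some members of those lists stood out, and a few of these are also known in macrophages. At least 1 TPM in every library was reached by 6 of 14 neutrophil and granulocyte precursor, 3 of 12 dendritic cell and 3 of 14 erythroid and megakaryocyte genes. The same held for 2 of 17 T and NK cell, 1 of 14 stromal and endothelial, 0 of 12 B cell and 0 of 10 mast cell, basophil and eosinophil genes. Cd4 stood at 69.11 ± 29.3 TPM and Il7r at 80.95 ± 43.4 TPM, while Cd3e, a chain of the T cell receptor complex, stood at 0.03 TPM. Pf4, a platelet chemokine gene also expressed by macrophages, stood at 974.0 ± 904 TPM. S100a9 stood at 456.6 TPM in replicate 3 and between 41.92 and 100.7 TPM in the other 3 libraries, and the granule genes Ngp and Ltf of neutrophil precursors were also highest in replicate 3, at 66.31 and 19.42 TPM.

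Genes of the alternative activation list were divided. Mrc1, the mannose receptor gene, stood at 330.6 ± 124 TPM and Stab1 at 309.1 ± 157 TPM, while Arg1 stood at 0.0225 ± 0.0263 TPM and Retnla had a count of 0 in every library. In that list 8 of 14 members reached 1 TPM in every library and 5 stayed below it in every library; macrophage identity genes lay 8.22 log2 units above it (8.3 to 8.78 in single libraries, adjusted permutation p = 2.29e-05). Markers of resident tissue macrophages lay 10.85 log2 units below macrophage identity genes (10.25 to 11.52 in single libraries, adjusted permutation p = 3.2e-05), with Cd5l at 604.7 ± 312 TPM and Siglec1 at 64.7 ± 22.1 TPM as the highest of 4 that reached 1 TPM in every library and Clec4f, Sall1 and Gata6 at a count of 0 in every library. All 4 libraries carried Xist, at 55.15 ± 10.4 TPM, and the Y-linked genes Uty, Kdm5d and Eif2s3y had a count of 0 in each.

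Glycolysis genes stood higher than genes of the tricarboxylic acid cycle. Gapdh stood at 1294 ± 280 TPM, Aldoa at 547.4 ± 63.1 TPM and Pkm at 526.3 ± 291 TPM, against 121.1 ± 41.1 TPM for Mdh2 and 116.0 ± 8.9 TPM for Sdha. All 16 genes of each list reached 1 TPM in every library. The medians differed by 1.45 log2 units (1.17 to 1.57 in single libraries, permutation p = 0.0162, adjusted 0.0173). With means of log2 values in place of medians the difference was 0.94 and no longer passed (adjusted permutation p = 0.141).

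The most abundant nuclear transcripts after the ribosomal RNA gene CT010467.1 were those of the ferritin chains, Fth1 at 26938 ± 4064 TPM and Ftl1 at 22526 ± 2426 TPM, followed by Lyz2. Psap, Ctsd, Ctsb, Gpnmb and Apoe stood between 11094 and 12986 TPM. Ribosomal RNA made up 12.34%, 3.258%, 4.437% and 6.985% of gene counts in replicates 1 to 4. Within the 15 highest nuclear genes, Gm28661, Gm10925 and Gm28437 are nuclear copies of mitochondrial sequence, and their reads cannot be told from those of mitochondrial genes, so their values are uncertain; the same holds for mt-Atp8, mt-Atp6 and mt-Co3.

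The 4 libraries differed by more than counting noise, and interferon-stimulated genes differed together. Rsad2, which encodes the antiviral protein viperin, stood at 132.9, 484.8, 191.5 and 575.4 TPM in replicates 1 to 4, Ifit1 at 60.23, 181.4, 50.42 and 288.4 TPM, and Gbp2 at 32.08, 225.9, 62.37 and 163.1 TPM. Of 25 interferon-stimulated genes, 20 were called variable (also 20 adjusted over the list alone) and 14 were highest in replicate 2 and 10 in replicate 4. The median SD over libraries was 0.71 log2 units, against 0.27 for random lists of matched level. The 2-sided random-list p was 0.0002, the smallest possible, and 0.00115 after adjustment. The median deviation of the members was -0.59, 0.62, -0.51 and 0.51 log2 units in replicates 1 to 4. Rsad2 (ENSMUSG00000020641.16) lies on chromosome 12 from 26442746 to 26456452.

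Several cytokine genes were called variable as well, while Cxcl1 and Cxcl2 were not. Il6 stood at 4.93, 36.95, 6.4 and 41.72 TPM in replicates 1 to 4, Il10, which encodes an anti-inflammatory cytokine, at 127.7, 575.0, 384.6 and 664.1 TPM, and Il12b at 45.36, 119.5, 17.06 and 80.06 TPM. Cxcl10, an interferon-inducible chemokine gene of the primary inflammatory list (ENSMUSG00000034855.13, chromosome 5 from 92346638 to 92348889), stood at 416.6, 1533, 247.0 and 1485 TPM. Cxcl1 stood between 1182 and 1448 TPM and Cxcl2 between 3037 and 3773 TPM. Of 24 primary inflammatory genes, 9 were called variable (also 9 adjusted over the list alone); their median SD was 0.33 log2 units against 0.32 in random lists (2-sided permutation p = 0.784, adjusted 0.82). Late inflammatory genes had a median SD of 0.6 against 0.29 (adjusted permutation p = 0.00591), but no shared movement was called: the SD of the median member deviation was 0.08 log2 units, while the list's median level was 10.1, 24.5, 11.7 and 23.9 TPM in replicates 1 to 4.

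**Figure D2:**
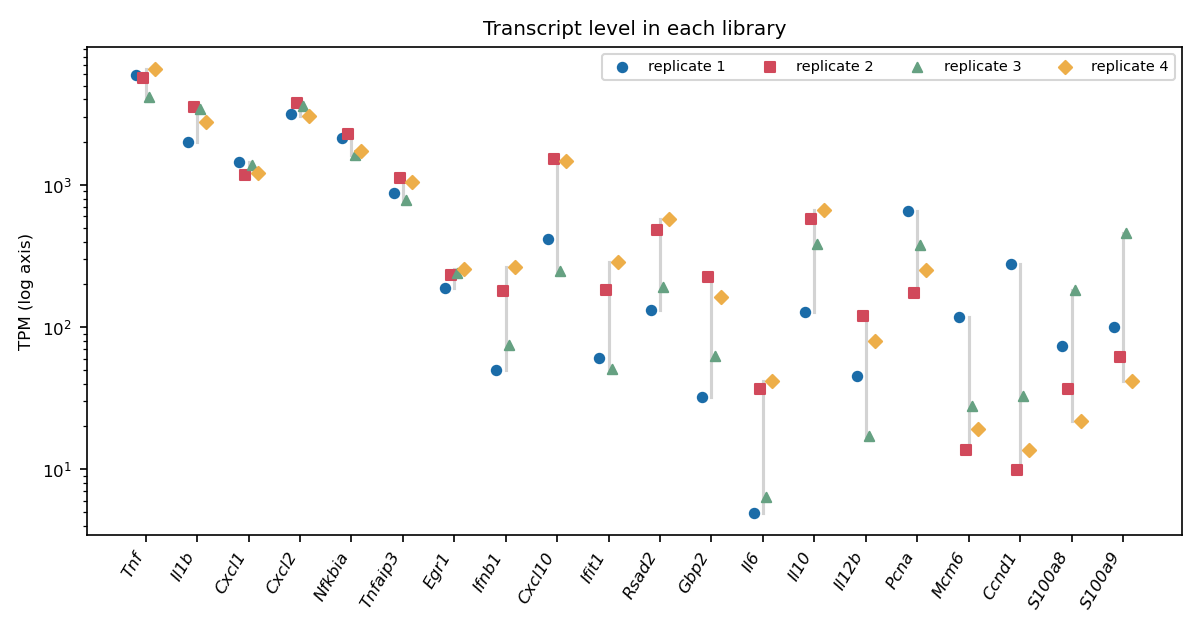
TPM on a log axis for 20 named genes, with 1 marker per library and a grey line from the lowest to the highest library. Tnf lies between 4126 and 6524 TPM, whereas Ifnb1 lies between 49.87 and 262.7 TPM and Il6 between 4.93 and 41.72 TPM.

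Cell cycle genes differed as well, and most were highest in replicate 1, the library with the highest share of ribosomal RNA (12.34% of counts against 3.258% to 6.985%). Mcm6, part of the replicative helicase, stood at 117.9 TPM in replicate 1 and at 13.7, 27.74 and 19.26 TPM in replicates 2 to 4, and Pcna at 652.6, 174.3, 376.8 and 252.1 TPM in replicates 1 to 4. Rrm2, a ribonucleotide reductase subunit gene, stood at 24.47, 1.28, 8.06 and 1.51 TPM. Of 21 proliferation genes, 19 were called variable (also 19 adjusted over the list alone), and 15 were highest in replicate 1 and 5 in replicate 3. The median deviation of the members was 1.09, -0.88, 0.32 and -0.68 log2 units in replicates 1 to 4, an SD of 0.92. The random-list p was 0.0001, the smallest possible, and 0.000383 after adjustment. Ccnd1, the cyclin D1 gene that growth factors are known to induce, stood at 278.2 TPM in replicate 1 and between 9.88 and 32.49 TPM in the other 3 libraries.

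Cholesterol synthesis genes moved together as well and were lowest in replicate 3. Of 19 members, 13 were called variable (also 13 adjusted over the list alone). The median deviation of the members was 0.45, 0.28, -0.77 and -0.03 log2 units in replicates 1 to 4; its median SD of 0.57 against 0.25 passed (adjusted permutation p = 0.00115) but not without replicate 3, where the SD was 0.27 (adjusted permutation p = 0.689). Antigen presentation genes were lowest in replicate 1 at a median deviation of -0.55 log2 units, and Cd86, a co-stimulatory receptor gene, stood at 9.24, 64.05, 33.99 and 41.51 TPM; 8 of 16 members were called variable (also 8 adjusted over the list alone). Immediate-early genes also spread more than matched lists, 0.5 against 0.28 log2 units (adjusted permutation p = 0.00591; 0.32 without replicate 1, adjusted permutation p = 0.00828), with Fosb at 2.43, 56.61, 47.47 and 74.32 TPM. Mitochondrially encoded genes (0.66 against 0.29, adjusted permutation p = 0.00368) and neutrophil genes (0.92 against 0.26, adjusted permutation p = 0.00115) did so too. The call of each of these last 2 lists was lost without replicate 3, at an adjusted random-list p of 0.359 and 0.0598. Genes of the Toll-like receptor 4 pathway spread less than matched lists, 0.19 against 0.26 log2 units (adjusted permutation p = 0.0394); this call was lost without replicate 1 (0.0502) and without replicate 3 (0.0946).

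In all, 8 of 23 lists spread more than matched lists (5 without replicate 3), and 14 had a median member deviation that differed more between libraries than in matched lists, by the statistic added after the data were seen. Beyond those described, these 14 lists include glycolysis (adjusted permutation p = 0.0237) and stress response (0.0222), both highest in replicate 1 with median member deviations of 0.29 and 0.31 log2 units. They also include inflammasome and cell death genes (0.0169), other Toll-like receptors (0.0222), negative feedback genes (0.0463), dendritic cell genes (0.0169), and erythroid and megakaryocyte genes (0.0222). The calls of these 7 lists were each lost with 1 library left out. The highest adjusted random-list p was 0.164 for glycolysis and other Toll-like receptors and 0.319 for negative feedback genes (each without replicate 2). It was 0.137 for stress response and inflammasome genes (without replicate 1). Without replicate 3 it was 0.615 for dendritic cell genes and 0.133 for erythroid and megakaryocyte genes. Macrophage identity genes (adjusted permutation p = 0.798), housekeeping genes (0.54) and tricarboxylic acid cycle genes (0.452) were not among them.

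**Figure D3:**
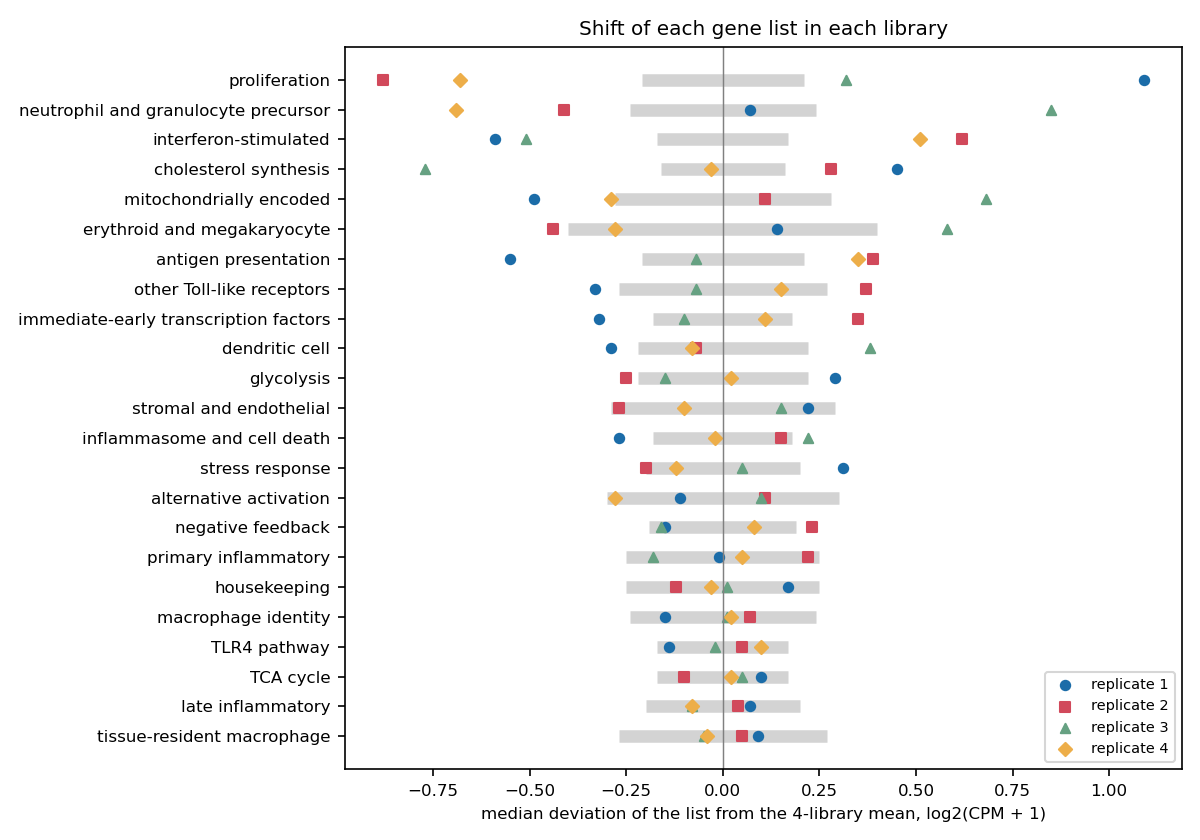
Median over the members of each of 23 gene lists of the deviation from a gene's mean over 4 libraries, in log2(CPM + 1). There is 1 marker per library. Grey bars reach to plus and minus the upper bound of the SD over libraries of matched random lists, which is no limit for a single marker. Interferon-stimulated genes lie at -0.59 and -0.51 in replicates 1 and 3 and at 0.62 and 0.51 in replicates 2 and 4, and proliferation genes reach 1.09 in replicate 1.

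Over all genes, 11152 of 12621 (88.4%) varied beyond counting noise in the chi-square test, and 4180 of them (33.1% of those tested) did so with at least a 2-fold range. The deposited credibility intervals of at least 1 pair of libraries did not overlap for 7945 of the 10250 genes at or above 1 TPM. The common biological coefficient of variation was 31% ± 7.1 (jackknife standard error over 4 libraries). Replicate 1 weighed heavily on both: without it the count of variable genes was 2097 and the coefficient 23.7%. Between pairs of libraries, the median absolute difference was lowest for replicates 2 and 4, at 0.17 log2 units, and highest for replicates 1 and 2, at 0.382. Among the variable protein-coding genes with a mean count of at least 100, Dmpk stood at 20.33 TPM in replicate 1 and at most 0.74 TPM elsewhere, Uhrf1, which maintains DNA methylation during replication, at 35.25, 1.16, 7.05 and 1.73 TPM, and Kynu, a kynurenine pathway gene, at 0.14, 7.66, 1.78 and 5.36 TPM. Several of the 15 with the highest ratio, among them B430305J03Rik, Chtf8, Gm20425, Gm20721, Hist2h3c1, Pagr1a and mt-Co3, can share reads with overlapping or near-identical genes and are uncertain.

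The contrast that follows a recorded technical difference, 6 read files in replicates 1 and 2 against 4 in replicates 3 and 4, called 0 of 12701 genes with edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, with 290 at an unadjusted p under 0.05. Other pairings of the libraries, added after the data were seen, were tested with edgeR on the same 12701 genes. Replicates 1 and 3 against 2 and 4 gave 1937 genes at an unadjusted p under 0.05. Replicates 1 and 4 against 2 and 3 gave 153, and 0 genes were called in each pairing. A share of 0.05 of the genes would pass by chance alone. Only replicates 1 and 3 against 2 and 4 exceeded that share, while the read file contrast and the remaining pairing lay below it. DESeq2 called 35 genes, 26 higher and 9 lower in the libraries with 6 read files. It was run on 55536 genes without that filter, and 40735 of them received no adjusted p. With edgeR 98 genes were called without replicate 2 and 1 without replicate 1, but either choice leaves a single library with 6 read files, so the spread comes from replicates 3 and 4 alone. In the edgeR test 86 of 445 pseudogenes, against 164 of 11380 protein-coding genes, had an unadjusted p under 0.05. The odds for pseudogenes were 14.2 times those of the other genes tested (Fisher's exact test p = 7.24e-57, with genes not independent). Of those 86 pseudogenes 75 were higher in the libraries with 6 read files, as were 112 of those 164 protein-coding genes. The median difference, 6 minus 4 read files, was 0.506 log2 units over all 445 pseudogenes and 0.023 over all 11380 protein-coding genes. Interferon-stimulated genes differed within each set of libraries: between replicates 1 and 2 alone and between replicates 3 and 4 alone the SD of their median deviation was 0.74 log2 units in both. The self-tests show that a 2-fold change would mostly be missed by this contrast.

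Transcript tables gave the same leading isoform for most genes. Of 9169 genes with at least 2 annotated transcripts and at least 1 TPM in every library, 8344 (91.0%) had the same transcript highest in both tables by mean TPM over libraries, and 88.8% to 91.1% did in single libraries. Il1rn, the interleukin-1 receptor antagonist gene, was led by Il1rn-201 (ENSMUST00000114482.2) with 76.9% ± 3.09 of its TPM in the first table and 70.4% ± 7.19 in the second. Myd88, the adaptor of most Toll-like receptors, was led by Myd88-201 at 99.1% ± 0.242 and 98.9% ± 0.516, and Pkm by Pkm-201 at 81.3% ± 2.84 and 76.9% ± 3.68. Nfkb1-206 led Nfkb1 with 38.7% ± 1.7 and 42.1% ± 2.42, and ENSMUST00000111194.7 led Cd44 with 57.5% ± 14.1 and 44.7% ± 17.3. All 15 genes fixed for this purpose had the same leading transcript in both tables.

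At the level of genes, 88.2% of 12159 genes lay within 2-fold of the median ratio of the 2 quantifications, and Spearman's rho across genes was 0.933 (genes are not independent replicates). The second quantification gave lower values by 0.344 log2 units at the median. TPM is relative, so transcripts that are high in only 1 of the tables lower all other values there. In the second transcript table Mir6236-201 had a mean of 124148 TPM, Klf10-204 of 41452 TPM, and Gm23935-201, Gm24245-201 and Gm24270-201 of 23518 TPM each, against 0 in the first. The lower median is therefore no measure of lower detection, and the part of it due to these transcripts was not computed. It placed 764 genes more than 10-fold above that median ratio and 163 more than 10-fold below it. The largest difference among protein-coding genes was that of Klf10, a TGFβ-inducible transcription factor gene chosen after its values were seen, at 16.11 TPM in the gene table and 41465 TPM in the second quantification.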

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

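All tests of explanations here were chosen after the pattern they bear on was seen, and the one on GC content and length was the only one whose own result had not been seen when its bound was set. Of 149 values examined for a single library far from the other 3 (named genes with a mean count of at least 10, list medians, class shares and depth), 10 stood out by Dixon's ratio. Chance alone marks about 1 in 20 values, here 7.5, but this rate does not hold here: 41 of the 116 genes had been picked for a high ratio between libraries and account for 7 of the 9 genes that stood out, against 2 of the other 75.

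Replicate 1 held 6 of these. Ccnd1 stood at 278.2 TPM against 9.88 to 32.49 TPM elsewhere, Mcm6 at 117.9 TPM against 13.7 to 27.74 TPM, and Ctla2a, which encodes a cysteine protease inhibitor, at 41.09 TPM against 1.08 to 4.8 TPM. Dmpk stood at 20.33 TPM against 0.2 to 0.74 TPM, Nptx1 at 4.71 TPM against 0.04 to 0.12 TPM, and the chemokine receptor gene Cx3cr1 at 1.85 TPM against 0.21 to 0.48 TPM. In replicate 2, Chtf8 stood at 3.82 TPM against 8.43 to 9.29 TPM elsewhere, and the median of the primary inflammatory list at 1425 TPM against 1040 to 1080 TPM. In replicate 3, S100a9 stood at 456.6 TPM against 41.92 to 100.7 TPM, and Tfrc, the transferrin receptor gene, at 651.5 TPM against 271.8 to 326.8 TPM. Outside the main measurement, the phiX row, which stands for a sequencing control, held 0.1128% of all counts on average and was left out of all tests.

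The interferon-stimulated list moved together between libraries, with median member deviations of -0.59, 0.62, -0.51 and 0.51 log2 units in replicates 1 to 4. With TPM rescaled without ribosomal and mitochondrial genes the SD over libraries was 0.59, above the upper bound of 0.16 from matched random lists. Rescaling multiplies all genes of a library by the same factor, so this decides nothing. Ribosomal RNA made up 12.34%, 3.258%, 4.437% and 6.985% of counts in replicates 1 to 4. This share fell from replicate 1 to 2 and rose from replicate 3 to 4, whereas the list rose both times. However, replicate 1 had the highest share and the lowest list deviation, and replicate 2 had the lowest share and the highest deviation. With 4 libraries this order cannot decide on ribosomal RNA content, which stays open. The mitochondrial share, 1.306%, 2.121%, 3.112% and 1.82% of counts, did not rank the libraries as the list did. The smaller of the differences within libraries with the same number of read files was 1.01 log2 units, against 0.02 between the sets, which argues against the read files. With the trend on GC content and length removed, an adjustment of 0.04 log2 units at the median and 0.19 at its upper bound, the SD was 0.64 before and after, with 0.17 as the bound. No biological explanation was tested, since the design has 1 group, and differences in standing interferon signalling, in culture or in timing stay open as hypotheses.

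Neutrophil and granulocyte precursor genes were highest in replicate 3. Of 14 members 13 were highest there, above the upper bound of 7 from matched random lists, but this count restates the pattern, so residual neutrophils or their precursors as a source were not put to a test that could support them and stay open. S100a9 stood at 456.6 TPM there, S100a8 at 181.2, Ngp at 66.31 and Ltf at 19.42 TPM, whereas Ly6g stood at 0.12 TPM; macrophage cultures can also carry S100a8 and S100a9 transcripts. A general lift of weakly expressed genes in that library is argued against only for the 9 members with a mean count of at least 10. Their median deviation was 0.85 log2 units, whereas the upper bound in random lists of the same level was 0.19. Members with lower counts were not tested, so a lift of the weakest genes stays open. Also highest in replicate 3 were 7 of 12 dendritic cell, 6 of 10 erythroid and megakaryocyte, and 5 of 7 mast cell, basophil and eosinophil genes, while T and NK cell (8 and 7 of 15), stromal and endothelial (6 and 5 of 12) and B cell genes (3 and 4 of 9) were mostly highest in replicate 1 or 3.

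Klf10-204 lies far higher in the second transcript table, at 73782, 88919, 2376 and 732.2 TPM in replicates 1 to 4, than in the first, at 0. This annotated transcript of 326 bases holds a run of 33 A. In the gene table the highest and lowest libraries of Klf10 differed 2.28-fold, not 121-fold as for the transcript. The other 5 Klf10 transcripts stood at 14.18, 10.77, 18.04 and 7.825 TPM in replicates 1 to 4 of the second table. These values argue against a change in transcription of the gene as a whole. They cannot decide on Klf10-204 alone, because it stood at 0 in the first table. Reads made only of A that are placed on long A runs are a candidate explanation: among other transcripts with a run of at least 31 A, 75 of 111 were higher in both of replicates 1 and 2 than in both of replicates 3 and 4 in the second table, against 55 of 276 with a run of 25 to 30 A (odds ratio 8.37, Fisher's exact test p = 1.22e-18, with transcripts not independent). Whether the libraries differ in such reads could be settled only from the reads, which were not used here.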

How the results depend on the processing

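The alternatives limited to libraries with the same number of read files, the rescaled TPM, the removal of the GC and length trend and the second quantification in the read file contrast were chosen after seeing the data, as was the statistic for lists that moved together. Of 223 alternative values of the 16 list comparisons, 220 kept their direction and their side of the threshold, those from rescaled TPM largely by construction. Sizes moved more: the difference of macrophage identity from B cell genes was 9.74 to 14.71 log2 units (lowest and highest with pseudocounts of 1 and 0.01 TPM), that from alternative activation genes 6.17 to 8.55 (lowest from 0.1 TPM), and that of primary inflammatory from negative feedback genes 2.12 to 3.28 (lowest without length correction). The glycolysis difference was 0.94 log2 units with means and did not pass. The Toll-like receptor 4 pathway difference, never past the threshold, was reversed at -0.27 with genes from 0.1 TPM and at -0.03 in replicates 3 and 4 only. B cell genes could not be compared from 0.1 TPM, as too few were left. The count of variable genes, 4180, was 2382 with a mean count of at least 100 (fewer genes tested), 2653 in replicates 1 and 2 only and 1284 in replicates 3 and 4 only (fewer libraries); leaving out 1 library gave 2097 to 3685, lowest without replicate 1. The coefficient of variation, 0.31, was 0.389 in replicates 1 and 2 only and 0.237 to 0.336 with 1 library left out, lowest without replicate 1. Lists above matched lists numbered 8, with 4 in replicates 1 and 2 only and 5 to 12 with 1 library left out, fewest without replicate 3. The 1 list below matched lists was the Toll-like receptor 4 pathway. This number became 0 with a mean count of at least 100, in the second quantification, in replicates 1 and 2 only and with the trend removed. With 1 library left out it was 0 to 1. Lists that moved together numbered 14, with 9 in replicates 1 and 2 only and 9 in replicates 3 and 4 only. Isoform agreement was 97.9% among genes led by a transcript with at least 60% of TPM. The read file contrast called 0 genes, but 35 with DESeq2, 18 without a filter, 10 in the second quantification and 0 to 98 with 1 library left out, most without replicate 2, where 1 library stands alone in its set. Apart from these constructions the cause was not tested. The mean TPM of named genes moved by more than 1 SD in 50 of 720 alternative values, 41 of them in the second quantification and 9 as posterior means. The remaining alternatives left out 1 library, which cannot move a mean over 4 libraries by 1 SD, so this rule could not mark them. The mean of Ccnd1, 83.58 TPM, was as low as 18.71 TPM with 1 library left out. Depth limits genes near the level of 3 counts, 0.0761 to 0.111 CPM.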

Other observations

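The genes and transcripts given here were chosen after their values were seen, and no further test was run on them. Interferon-stimulated and cell cycle genes deviated with opposite signs in each of 4 libraries, too few for a correlation. This was not particular to cell cycle genes. The neutrophil (0.07, -0.41, 0.85 and -0.69), erythroid and megakaryocyte, stromal and endothelial, stress response and housekeeping lists had the same signs as the cell cycle genes. By the median of its members, the interferon-stimulated list deviated by -0.59, 0.62, -0.51 and 0.51 log2 units in replicates 1 to 4 and the proliferation list by 1.09, -0.88, 0.32 and -0.68. Antigen presentation genes lay at -0.55, 0.39, -0.07 and 0.35. Clec10a, a lectin gene of alternatively activated and dendritic cells, stood at 7.19, 80.85, 32.64 and 49.24 TPM, and the antigen-presenting class II genes H2-Aa and H2-Eb1 at 111.6, 203.9, 168.7 and 240.9 TPM and at 60.03, 150.8, 128.7 and 173.7 TPM. Pf4 stood at 2237, 404.6, 1009 and 245.8 TPM, and Selenop, a selenium transport protein gene, at 2704, 11211, 7556 and 7633 TPM.

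Not every member of a list went with it. Ifi205 stood at 238.3, 205.4, 284.7 and 79.58 TPM, lowest in replicate 4, unlike the other interferon-stimulated genes described. Mki67, a common marker of cycling cells, stood at 38.3, 49.2, 34.61 and 27.73 TPM and was highest in replicate 2, while Top2a stood at 32.54, 3.84, 19.42 and 4.53 TPM. In the primary inflammatory list Ccl2 and Ccl7, genes of monocyte-attracting chemokines, stood at 4614, 2586, 1654 and 1016 TPM and at 3585, 1777, 1482 and 564.8 TPM. The lipoprotein lipase gene Lpl, in the macrophage identity list, stood at 1098, 208.0, 1502 and 501.1 TPM.

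Further transcripts differed between the tables. Mir6236-201, an annotated microRNA model of 123 bases, had a mean of 124148 TPM in the second transcript table and 0 in the first, and each of the 57-base models Gm23935-201, Gm24245-201 and Gm24270-201 had a mean of 23518 TPM against 0. Of the 10 genes that edgeR called in the second quantification between libraries with 6 and 4 read files, all were higher in those with 6, among them the pseudogenes Gm10359 and Gm12671 with identical values; Gm37144 was higher by 6.22 log2 units (SE 0.31, adjusted p = 0.0157).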
